A study of Mus musculus with 10 samples.

How the data were processed

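Mouse RNA was measured in 10 2-colour hybridizations on 4 Agilent microarrays, which covered 4 experiments. In every hybridization the Cy3-labelled sample was channel 1 and the Cy5-labelled sample was channel 2, and the dyes were never swapped. Experiment 1 compared whole lung after infection with recombinant Shigella flexneri (Cy5) with lung after wild-type Shigella flexneri (Cy3). Experiment 2 compared lung from an allergy model with induction by ovalbumin (OVA, Cy5) with lung without induction (Cy3). Experiment 3 compared sorted liver cells, negative for CD3 and positive for NK1.1, of Listeria monocytogenes-infected (Cy5) and naive (Cy3) gene-deficient Rag-/- mice. Experiment 4 repeated the allergy comparison in mice that lacked their own interferon gamma (IFN-g) gene and carried a transgene for it. Arrays 2, 3 and 4 were new when they received experiments 2, 3 and 4; they were stripped and received experiment 1, then stripped again and received their first experiment once more. Array 1 was new and received experiment 1 alone. Experiment 1 therefore had 4 hybridizations and each of the others had 2; replicate 1 of every experiment is the one on a new array.

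The deposited values were log ratios of the 2 channels, 1 per probe and hybridization, with both signs and column medians between 0 and 0.00244. The labels name no scanner setting, background correction or normalization. The base of the logarithm is not stated; the deposited values were taken as log10, the Agilent convention for log ratios, and were converted to log2. If they were log2 as deposited, every printed log2 value and SD would be smaller by the same factor; calls and p values would stay as they are, and counts at a fixed log2 ratio would not. The orientation is not stated either. Values were read as Cy5 over Cy3, which is likely only. The basis was fixed before the data were examined: the type 2 allergic airway list had a median of 1.23 in experiment 2, and the interferon gamma response and interferon stimulated lists had medians of 0.09 and 0.04 in experiment 3. The stimulated list did not pass there (limma camera, adjusted p = 0.736) and the response list lost its call with an estimated correlation (adjusted p = 0.358), so experiment 3 gave little support for the direction. The type 2 list in experiment 2 is therefore not independent evidence of direction. No intensities or background values came with the ratios, and the number of hybridizations limits the precision. Between 41 and 385 values per hybridization were exactly 0 (0.512 to 4.80%), for a reason not stated. From the first to the third hybridization their number rose on array 2 (41, 124 and 229) and on array 4 (46, 238 and 385). It fell on array 3 (189, 66 and 65).

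The table held 8014 probes and 1 missing value. The annotation gave 1 gene symbol for 4654 probes, several for 73 and none for 3287; the 4654 probes stood for 4331 genes, of which 294 had more than 1 probe. Gene positions refer to the mouse assembly GRCm38.p6. Each hybridization was centred on its median. Probes needed a value in every hybridization of the tested experiment and in at least 8 of 10. A single model of 4 experiment means over all 10 hybridizations was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3. The mean log2 ratio of each experiment was tested against 0, and the difference between experiments 2 and 4 was tested as a contrast, with Benjamini-Hochberg (BH) adjustment over probes and a threshold of 0.05. The fit had 6 residual degrees of freedom and a prior of 1.90. Hybridizations of 1 experiment repeated the same comparison of samples, and the labels do not say whether the same RNA extracts were used. The biological n was 1 per experiment, so SD, n and p values describe hybridizations and never variation between mice.

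Genes named in the text followed a rule set before the data were examined: in each experiment the 12 highest and 12 lowest mean ratios among probes past the threshold with 1 symbol and the same sign in every hybridization, 1 probe per gene, and for the contrast the 8 highest and 8 lowest. Members of the gene lists are named besides, by largest absolute ratio or because they passed the test. For gene lists, probes of a gene were averaged and the same model was fitted to 4331 genes. Of 22 lists set beforehand, 21 had at least 3 measured genes and were tested with camera (inter-gene correlation 0.01), two-sided, with BH over 84 tests in the 4 experiments and over 21 tests in the contrast. Camera with an estimated correlation and fry were run beside it. Members past the gene test were counted over all genes and adjusted over the list alone.

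Agreement between hybridizations was measured by Pearson's r across probes, by root-mean-square differences, by standardized major axis slopes, and by slopes on the preceding hybridization of the same array, with exact permutation tests where the design allowed one. These used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. The model was tested on simulated data: among 50 changed probes per size, a log2 change of 1 was recovered in 92%, 86%, 86% and 84% of cases in experiments 1 to 4 and in 64% in the contrast, and a change of 0.25 in 38%, 24%, 26%, 16% and 4%. Each simulated set held 8014 probes, and 14, 14, 5, 8 and 5 of those left without a change were called. The simulated noise was normal, with the same SD for a probe in every experiment. The measured spread was larger in experiments 2, 3 and 4 than in experiment 1. Recovery and false calls were thus not tested at the spread of each experiment. Camera recovered 5 of 5 lists shifted by 0.3 and called 0 of 79 other tests, at adjusted p of 0.05. These were random lists of genes simulated as independent, so the result does not cover lists whose members vary together. An added carry-over slope of 0.1 was recovered as 0.0944 for the second hybridization and 0.100 for the third. The addition was a share of the same log ratios on which the slope was fitted, so this checks the calculation alone. It does not show how much real carry-over could be detected. For the second hybridization the exact permutation p was then 0.167, the smallest possible.

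Alternatives covered centring, scaling, probe filters, an array block, a robust prior, the hybridizations in the fit, each experiment against the mean of the other 3, rank correlation, the probe kept per gene, and each of the 10 hybridizations left out in turn. Array quality weights, a fit of experiments 2, 3 and 4 alone, and a fit without probes holding an exact 0 were added after seeing the data. The sex-linked list had 1 measured gene and was not tested.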

Results

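The data were log2 ratios of 8014 mouse probes in 10 hybridizations: 4 of experiment 1 (lung, recombinant against wild-type Shigella flexneri) and 2 each of experiment 2 (lung, OVA allergy model with against without induction), experiment 3 (liver CD3-negative NK1.1-positive cells of Listeria-infected against naive Rag-/- mice) and experiment 4 (the allergy comparison in IFN-g transgenic mice). The series was made to examine a protocol for stripping and reusing arrays. Ratios are given as mean ± SD over hybridizations of the same comparison, n = 4 in experiment 1 and n = 2 in the others. They are Cy5 over Cy3 and rest on a log10 reading of the deposited values, both likely but not stated by the labels. There was 1 biological comparison per experiment. The SD of all ratios in a hybridization was between 0.341 and 0.425. The median SD of a probe over repeated hybridizations was 0.0905, 0.0748, 0.128 and 0.0948 in experiments 1 to 4. Such a median runs lower with 2 hybridizations than with 4, so experiment 1 cannot be compared with the others by it. From differences between pairs across all probes, the SD of a hybridization was 0.177 to 0.205 in experiment 1. It was 0.220, 0.258 and 0.274 in experiments 2, 3 and 4, while the model gave each probe 1 error estimate for all experiments.

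Experiment 1 asked how the lung response to recombinant Shigella differed from that to wild-type bacteria. Lung infected with the recombinant strain had higher transcripts of Il10, an anti-inflammatory cytokine, at 2.09 ± 0.10 (SD, n = 4), and of Csf3, the granulocyte colony-stimulating factor, at 1.70 ± 0.05. Il6 rose by 1.27 ± 0.15, the interleukin 1 family cytokine Il1f6 by 1.55 ± 0.08, and the interleukin 1 receptor gene Il1r1 by 1.33 ± 0.07. In the opposite direction, Lrat, which esterifies retinol, was at -2.16 ± 0.05 and the receptor gene Calcrl at -2.05 ± 0.06. The decoy interleukin 13 receptor Il13ra2 was at -1.95 ± 0.15 and the interleukin 12 receptor chain Il12rb1 at -1.59 ± 0.11. Il10 (Entrez 16153) lies on chromosome 1 at 131019845 to 131024970 and Lrat (Entrez 79235) on chromosome 3 at 82892582 to 82903974, both protein-coding genes.

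Inflammatory cytokines and chemokines rose as a group in experiment 1. Of 34 measured members, 25 were higher, 2 lower (Cxcl13 at -0.48 ± 0.08 and Il18 at -0.35 ± 0.11) and 7 did not pass. Adjusted over the list alone, 27 were higher and 2 lower. Their median log2 ratio was 0.72 (limma camera, adjusted p = 3.45e-08). Examples are the NF-kB pathway gene Nfkbiz at 1.21 ± 0.07, the neutrophil chemoattractants Cxcl2 at 1.18 ± 0.45 and Cxcl1 at 0.99 ± 0.02, and Il17a at 1.14 ± 0.06. Interferon gamma response genes fell: 22 of 25 were lower, 2 did not pass, and the chemokine gene Cxcl10 was higher at 0.58 ± 0.04. The median of this list was -0.67 (camera, adjusted p = 3.64e-10), and 23 were lower and 1 higher adjusted over the list alone. Among them were the interferon-inducible GTPase genes Tgtp1 at -1.19 ± 0.05, Gbp4 at -1.12 ± 0.04 and Igtp at -1.07 ± 0.04, and the immunoproteasome subunit Psmb9 at -0.98 ± 0.08. Both list calls held with an estimated correlation (adjusted p = 0.0436 each).

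Interferon stimulated genes were lower in experiment 1 in 8 of 11 cases, including the nucleic acid sensor Zbp1 at -1.29 ± 0.31 and the antiviral membrane protein Bst2 at -1.10 ± 0.06, while Ifi202b was higher at 0.38 ± 0.15. The list median was -0.27 (camera, adjusted p = 0.00900), with adjusted p = 0.109 with an estimated correlation. Of these genes, 9 were lower and 1 higher adjusted over the list alone. Of 11 neutrophil markers 6 rose, led by Itgb2l at 1.07 ± 0.05, the granule protein Ngp at 1.07 ± 0.06 and the receptor Trem1 at 1.01 ± 0.14. The receptor for granulocyte colony-stimulating factor Csf3r was lower at -0.28 ± 0.09, and adjusted over the list alone the counts were also 6 and 1. Their median was 0.27 (camera, adjusted p = 0.0397), and adjusted p = 0.146 with an estimated correlation. Endothelial and macrophage markers had medians of -0.34 and -0.26 and did not pass (camera, adjusted p = 0.0587 and 0.0855), although Icam2 was at -0.96 ± 0.04 and the macrophage gene Adgre1 at -1.08 ± 0.05. Immediate early and heat shock genes had a median of 0.26, cell cycle genes -0.19 and MHC class II genes -0.16, none past the test (camera, adjusted p = 0.0827, 0.108 and 0.265). Type 2 airway genes had a median of 0.13 and a mean of -0.09, of opposite signs (camera, adjusted p = 0.996).

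Also higher in experiment 1 were the phosphate-regulating hormone Fgf23 (1.60 ± 0.10), the glutathione transferase Gsta2 (1.56 ± 0.18) and the nuclear lamin Lmnb1 (1.45 ± 0.04). So were the interleukin 18 receptor chain Il18rap (1.39 ± 0.06), 1700001J03Rik (1.34 ± 0.43), Igfbp3 (1.28 ± 0.07) and the calcitonin receptor Calcr (1.22 ± 0.10). Ccn5 (-1.72 ± 0.10), Plaat3 (-1.51 ± 0.06) and H2-T24 (-1.39 ± 0.03) were lower. So were Aif1 (-1.35 ± 0.05), Prkcz (-1.33 ± 0.09), the lymphatic growth factor Vegfd (-1.31 ± 0.10) and Prkg2 (-1.28 ± 0.07). In all, limma called 3204 of 8013 probes. Of these 1542 were higher and 1662 lower, and 50 and 50 had an absolute log2 ratio of at least 1. The call for neutrophil markers ended without replicate 2 (adjusted p = 0.0503, limma camera) or without replicate 4 (0.0545), with 1 probe per gene (0.0513), and against the mean of the other 3 experiments (0.25).

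Experiment 2 asked what OVA induction changed in the lung of the allergy model. Induced lung had higher transcripts of the eosinophil- and monocyte-attracting chemokine Ccl8 (3.75 ± 0.10, SD, n = 2), the arginine-degrading enzyme Arg1 (3.58 ± 0.45), the goblet cell product Clca1 (3.49 ± 0.27), the airway mucin Muc5ac (2.83 ± 0.15) and the acute phase protein Saa3 (2.88 ± 0.09). The lowest ratios belonged to the glutathione transferase Gsta2 (-2.47 ± 0.50), the adipocyte hormone Adipoq (-1.46 ± 0.09) and Oxct2a (-1.32 ± 0.03). Ccl8 (Entrez 20307) lies on chromosome 11 at 82115185 to 82116799 and Gsta2 (Entrez 14858) on chromosome 9 at 78331018 to 78347192, both protein-coding.

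Type 2 allergic airway genes were higher in 10 of 15 cases in experiment 2, 0 were lower and 5 did not pass, with the same counts adjusted over the list alone. The median was 1.23 (limma camera, adjusted p = 1.13e-06). This list also set the reading of the ratio's direction. Ccl17, a chemokine for type 2 helper T cells, was at 2.25 ± 0.02. Macrophage markers rose in 17 of 23 cases with a median of 1.17 (camera, adjusted p = 1.55e-08), and 18 were higher and 1 lower adjusted over the list alone. Among them were the complement genes C1qb at 2.26 ± 0.06 and C1qa at 1.88 ± 0.03 and the integrin Itgax at 1.65 ± 0.06, while Lyz1 was lower at -0.46 ± 0.07. Cell cycle genes rose in 24 of 29 cases, or 27 adjusted over the list alone, with a median of 1.06 (camera, adjusted p = 5.63e-13). They included the mitotic genes Birc5 at 2.52 ± 0.19 and Top2a at 1.89 ± 0.21. MHC class II genes were higher in 11 of 14 cases, also adjusted over the list alone, with a median of 0.74 (camera, adjusted p = 1.43e-05). Ctss, a protease of antigen processing, was at 1.69 ± 0.03 and H2-Ab1 at 1.21 ± 0.03. Acute phase and complement genes rose in 9 of 13 cases with a median of 0.55 (camera, adjusted p = 5.72e-06), and 9 were higher and 1 lower adjusted over the list alone. The immunoglobulin transporter Pigr was at 2.22 ± 0.07. Interferon gamma response genes rose in 22 of 25 cases, also adjusted over the list alone, with a median of 0.55 (camera, adjusted p = 9.58e-13). They were led by the T cell chemoattractants Cxcl9 at 2.48 ± 0.34 and Cxcl10 at 1.80 ± 0.22. Endothelial markers fell in 10 of 15 cases, also adjusted over the list alone, with a median of -0.32 (camera, adjusted p = 3.09e-04), such as the vascular receptor Kdr at -0.54 ± 0.02. These 7 calls held with an estimated correlation (adjusted p = 0.0466 for cell cycle genes and 0.0436 for the other 6).

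A further 4 lists passed in experiment 2 with the preset correlation. Inflammatory cytokines had 15 of 34 members higher and 2 lower (16 and 3 adjusted over the list alone). Ccl9 was at 3.00 ± 0.02, the B cell chemoattractant Cxcl13 at 2.65 ± 0.10 and Ptgs2 at -0.69 ± 0.01. The median was 0.25 (camera, adjusted p = 7.19e-04; adjusted p = 0.107 with an estimated correlation). Immediate early and heat shock genes had 12 of 25 members lower and 0 higher (13 and 1 adjusted over the list alone), such as Klf2 at -0.84 ± 0.09 and the phosphatase Dusp1 at -0.65 ± 0.00. Their median was -0.22 (camera, adjusted p = 0.00255; adjusted p = 0.155 with an estimated correlation). T cell genes had 9 of 19 members higher (10 adjusted over the list alone), with the T cell receptor component Cd3g at 0.84 ± 0.06. Their median was 0.30 (camera, adjusted p = 0.00767; adjusted p = 0.115 with an estimated correlation). B and plasma cell genes had 8 of 20 higher and 1 lower, also adjusted over the list alone, with the transcription factor Irf4 at 0.89 ± 0.12. Their median was 0.16 (camera, adjusted p = 0.0489; adjusted p = 0.197 with an estimated correlation).

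Other named genes higher in experiment 2 were the metalloprotease inhibitor Timp1 (2.89 ± 0.03) and the kinase Matk (2.47 ± 0.08). Those lower were Fgfbp1 (-1.18 ± 0.13), the cystine transporter Slc7a11 (-1.16 ± 0.33), Lrat (-1.15 ± 0.07), and Pgrmc1 (-1.09 ± 0.07). The calcium channel Ryr2 (-1.05 ± 0.54), the tuft cell factor Pou2f3 (-1.01 ± 0.41), Prkg2 (-0.97 ± 0.17), Esd (-0.97 ± 0.08) and Gsta3 (-0.93 ± 0.00) were lower too. Limma called 2100 of 8014 probes, 1102 higher and 998 lower, of which 167 and 14 had an absolute log2 ratio of at least 1. The count was 1109 without replicate 1, where Ryr2 lost its call (-0.67, limma adjusted p = 0.191), and 1171 without replicate 2. It was 1140 when experiment 1 was left out of the fit, an alternative chosen after seeing the data, and 0 (limma; 2622 at an unadjusted p under 0.05) from the 2 hybridizations alone. The B cell call ended without replicate 1 (limma camera, adjusted p = 0.101), with 1 probe per gene (0.0513) and without experiment 1 (0.0556), and it held in 6 of 10 settings with 1 hybridization left out. Set against the mean of the other 3 experiments, T cell (0.0988) and endothelial lists (0.142) lost their calls and the inflammatory list median turned to -0.0581 (0.654).

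**Figure D1:**
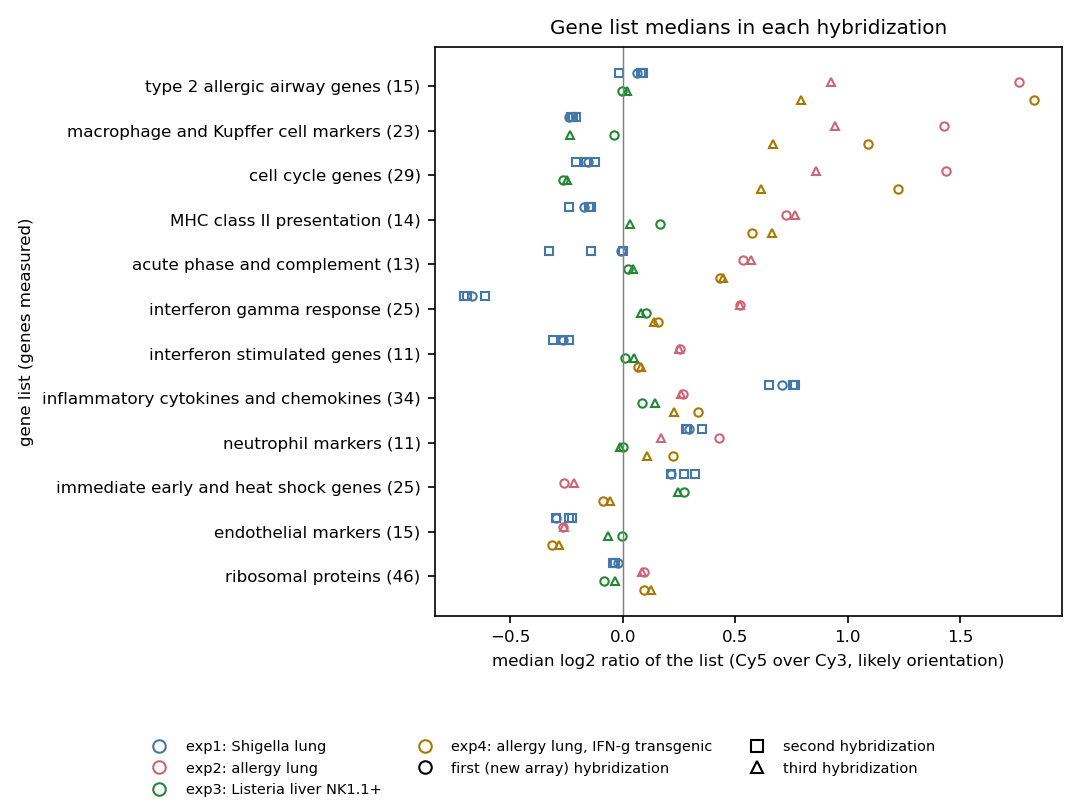
Median log2 ratio (horizontal axis, Cy5 over Cy3 as the likely orientation) of 12 gene lists in each of the 10 hybridizations; colours give the experiment and symbols its place among the hybridizations of an array, with the number of measured genes after each list name. Interferon gamma response medians of experiment 1 lie below 0 in all 4 hybridizations, and type 2, macrophage and cell cycle medians of experiments 2 and 4 lie above 0 in both, with lower values on the third hybridization than on the first.

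Experiment 3 asked how Listeria infection changed sorted liver NK1.1-positive cells. Cells of infected mice had higher transcripts of the heat shock gene Hspa1a (2.43 ± 0.62, SD, n = 2), the cytokine signalling inhibitor Socs3 (1.83 ± 0.10), the macrophage growth factor Csf1 (1.41 ± 0.14) and Ifng, the main cytokine product of NK cells (1.37 ± 0.01). The lowest ratios belonged to the fatty acid desaturase Scd2 (-1.37 ± 0.27), the cytokinesis gene Ect2 (-1.34 ± 0.23), Smpdl3a (-1.27 ± 0.26) and Atp6ap2 (-1.24 ± 0.12). Ifng (Entrez 15978) lies on chromosome 10 at 118441046 to 118445894 and Scd2 (Entrez 20250) on chromosome 19 at 44293676 to 44306864, both protein-coding.

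NK and cytotoxic genes went both ways in experiment 3, with 7 of 27 higher, 9 lower and 11 not past the gene test (9 higher and 10 lower adjusted over the list alone), and the list as a whole did not pass (median -0.05, mean 0.07, of opposite signs; limma camera, adjusted p = 0.834). Higher were Ifng, the chemokine Xcl1 (1.07 ± 0.03), Lilr4b (1.1 ± 0.12) and the interleukin 2 receptor chain Il2rb (0.77 ± 0.04). Lower were the lectin-like receptor genes Klrd1 (-0.60 ± 0.05), Klra1 (-0.59 ± 0.02), Klrb1c, which encodes NK1.1 (-0.56 ± 0.04), Klrc1 (-0.54 ± 0.04) and Klrg1 (-0.54 ± 0.05), and the chemokine Ccl5 (-0.47 ± 0.04). Immediate early and heat shock genes rose in 12 of 25 cases and 2 fell (13 and 2 adjusted over the list alone), with Gadd45b at 1.02 ± 0.06, the chaperone Hsph1 at 0.96 ± 0.10 and Klf2 at -0.43 ± 0.01. The median was 0.26 (camera, adjusted p = 2.98e-04; adjusted p = 0.109 with an estimated correlation).

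Interferon gamma response genes had 9 of 25 members higher and 5 lower in experiment 3, also adjusted over the list alone. The transcription factors Irf8 (1.03 ± 0.03) and Irf1 (0.77 ± 0.06) and the chemokine Cxcl10 (1.14 ± 0.28) were higher, and B2m, the light chain of MHC class I, was lower (-0.41 ± 0.02). The list median was 0.09 (camera, adjusted p = 0.0304; adjusted p = 0.358 with an estimated correlation). Inflammatory cytokines had 6 of 34 higher and 2 lower (6 and 1 adjusted over the list alone), with Csf2 at 0.72 ± 0.09, the NF-kB inhibitor Nfkbia at 0.66 ± 0.00 and Cxcl13 at -0.57 ± 0.26. Their median was 0.11 (camera, adjusted p = 0.0350; adjusted p = 0.255 with an estimated correlation). Markers of other liver cells did not pass as lists: 5 of 23 macrophage and Kupffer cell markers were lower and 0 higher (median -0.12, camera adjusted p = 0.172), among them Fcgr3 at -0.85 ± 0.02. Hepatocyte markers had a median of -0.32 over 4 genes (camera, adjusted p = 0.393), with Ambp at -0.86 ± 0.65.

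Other named genes higher in experiment 3 were Dgat1 (1.5 ± 0.12), Erdr1 (1.33 ± 0.05), the AP-1 factor Jund (1.23 ± 0.03), Mettl1 (1.22 ± 0.32), the tyrosine kinase Fes (1.17 ± 0.00) and Cdk5r2 (1.12 ± 0.04). Lower were Nptn (-1.18 ± 0.01), Sptssa (-1.18 ± 0.07), Mat2b (-1.13 ± 0.00), Rnf103 (-1.13 ± 0.00), Smim3 (-1.11 ± 0.37), the selenium carrier Selenop (-1.11 ± 0.02), the lipid scavenger receptor Cd36 (-1.10 ± 0.74) and the lipid-presenting molecule Cd1d1 (-1.09 ± 0.08). Limma called 2150 of 8014 probes, 986 higher and 1164 lower, of which 25 and 29 had an absolute log2 ratio of at least 1. Cd36 lost its call without replicate 1 (-0.57, limma adjusted p = 0.0538). With alternatives chosen after seeing the data, the count was 1179 with array quality weights and 1298 without experiment 1; it was 0 (limma; 1632 at an unadjusted p under 0.05) from the 2 hybridizations alone. The interferon call ended without replicate 1 (limma camera, adjusted p = 0.120), with 1 probe per gene (0.0646) and against the mean of the other 3 experiments (0.0688). The inflammatory list call ended without replicate 2 (limma camera, 0.133), and its median turned to -0.340 against the other experiments (0.0163).

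Experiment 4 asked the same of OVA induction in IFN-g transgenic mice lacking their own IFN-g gene. The highest ratios were again those of Ccl8 (3.53 ± 0.31, SD, n = 2), Arg1 (2.93 ± 0.72), Clca1 (2.89 ± 0.96) and Cxcl13 (2.60 ± 0.16), and Gsta2 had the lowest (-1.92 ± 0.52). Type 2 airway genes were higher in 8 of 15 cases and lower in 0, also adjusted over the list alone, with Ccl17 at 2.12 ± 0.12, the mucin Muc5ac at 2.05 ± 0.04 and a median of 1.28 (limma camera, adjusted p = 1.29e-06). Cell cycle genes rose in 22 of 29 cases, or 24 adjusted over the list alone (median 0.89, camera adjusted p = 9.58e-13), with the proliferation marker Mki67 at 1.48 ± 0.16. Macrophage markers rose in 17 of 23 cases (median 0.88, camera adjusted p = 1.00e-08; 17 higher and 1 lower adjusted over the list alone), with C1qb at 1.90 ± 0.06. MHC class II genes rose in 9 of 14 cases, also adjusted over the list alone (median 0.58, camera adjusted p = 1.38e-05), with Ctss at 1.17 ± 0.01. Acute phase genes rose in 7 of 13 cases, also adjusted over the list alone (median 0.34, camera adjusted p = 5.86e-05), with Saa3 at 2.22 ± 0.03 and Pigr at 1.95 ± 0.06. Ribosomal protein genes rose in 17 of 46 cases, or 18 adjusted over the list alone, by little (median 0.09, camera adjusted p = 0.00553), with Rps26 at 0.43 ± 0.03. These 6 calls held with an estimated correlation (adjusted p = 0.0466 for cell cycle and ribosomal genes and 0.0436 for the other 4).

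Inflammatory cytokines in experiment 4 had 16 of 34 members higher and 3 lower, also adjusted over the list alone, with Ccl9 at 2.25 ± 0.06, Cxcl5 at 1.39 ± 0.14 and Il12a at -0.60 ± 0.40. The median was 0.29 (camera, adjusted p = 1.23e-04; adjusted p = 0.0710 with an estimated correlation). Endothelial markers had 8 of 15 lower and 1 higher (9 and 1 adjusted over the list alone), with Sox17 at -0.48 ± 0.04 and Car4 at 0.24 ± 0.02. Their median was -0.30 (camera, adjusted p = 0.00424; adjusted p = 0.0651 with an estimated correlation). T cell genes had 6 of 19 higher (9 adjusted over the list alone), with Cd3d at 0.61 ± 0.05. Their median was 0.27 (camera, adjusted p = 0.00602; adjusted p = 0.109 with an estimated correlation). Interferon gamma response genes had 11 of 25 higher and 1 lower (12 and 1 adjusted over the list alone), with the signalling inhibitor Socs1 at 1.04 ± 0.08. Their median was 0.11 (camera, adjusted p = 0.00843; adjusted p = 0.311 with an estimated correlation).

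Other named genes higher in experiment 4 were Timp1 (2.29 ± 0.08), Birc5 (2.01 ± 0.35) and Matk (2.01 ± 0.23). Lower were Phf10 (-1.56 ± 0.42), AV064505 (-1.48 ± 0.18), Slc7a11 (-1.39 ± 0.03), Lrat (-1.34 ± 0.06), and Epha6 (-1.30 ± 0.79). So were Gpr12 (-1.28 ± 0.70), Klf11 (-1.08 ± 0.19), Ddx46 (-0.91 ± 0.61), the clock gene Nr1d2 (-0.88 ± 0.09), Mtmr4 (-0.87 ± 0.53) and Esrrg (-0.87 ± 0.37). Limma called 1777 of 8014 probes, 931 higher and 846 lower, of which 108 and 12 had an absolute log2 ratio of at least 1. Without replicate 1, Ddx46 (-0.47, limma adjusted p = 0.109), Gpr12 (-0.78, 0.163) and Esrrg (-1.13, 0.0662) lost their calls. Without replicate 2, limma calls were lost by Epha6 (-0.74, 0.264), Nr1d2 (-0.81, 0.0976) and Esrrg (-0.61, 0.336), and the count was 923. Esrrg held in 2 of 10 settings with 1 hybridization left out. The count was 2884 with the array as a random block, 1184 against the mean of the other 3 experiments, 693 without experiment 1 in the fit (chosen after seeing the data) and 0 (limma; 1805 at an unadjusted p under 0.05) from the 2 hybridizations alone. T cell and interferon list calls ended without replicate 1 (limma camera, adjusted p = 0.0534 each) and the ribosomal call without replicate 2 (0.0903). Against the mean of the other 3 experiments, T cell (0.222), interferon (0.141) and endothelial lists (0.642) lost their calls and the inflammatory median turned to -0.126 (0.650).

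The ratios of experiments 2 and 4 were compared directly, since both measured OVA induction. The largest difference was that of the interferon-inducible chemokine Cxcl9, at 2.48 in experiment 2 and -0.17 in experiment 4, a difference of 2.65 ± 0.20 (SE; limma, adjusted p = 0.00194). Ifng itself was at 0.82 and -0.03 (difference 0.86, limma adjusted p = 0.0254) and Cxcl10 at 1.80 and 0.41 (1.39, 0.0154). The GTPase genes differed too, Igtp at 0.93 and -0.15 (1.08, 0.00248), Gbp4 at 0.68 and -0.14 (0.83, 0.00538) and Gbp2 at 0.55 and -0.11 (0.66, 0.0327), all by limma. Interferon gamma response genes as a list differed by a median of 0.30 (camera, adjusted p = 1.69e-20; adjusted p = 0.0222 with an estimated correlation). Of 25 members 8 were higher in experiment 2 and 0 lower, and 20 were higher adjusted over the list alone. Adipoq was at -1.46 and -0.07 (-1.38, limma adjusted p = 0.00207) and Oxct2a at -1.32 and 0.26 (-1.58, 5.67e-04). Cxcl9 (Entrez 17329) lies on chromosome 5 at 92321331 to 92328079, near Cxcl10 (Entrez 15945) at 92346638 to 92348889.

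**Figure D2:**
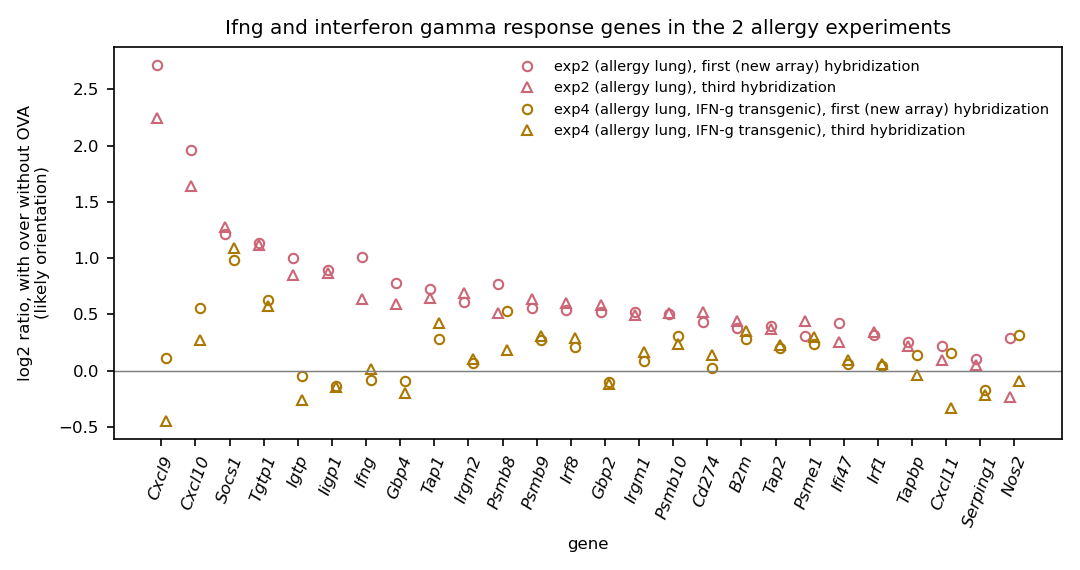
Log2 ratio with over without OVA (vertical axis, likely orientation) of Ifng and 25 interferon gamma response genes (horizontal axis) in each hybridization of experiments 2 and 4; circles are first and triangles are the third hybridizations. Cxcl9 lies above 2 in both hybridizations of experiment 2 and near or below 0 in both of experiment 4.

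Other genes higher in experiment 2 than in experiment 4 were AV064505 (1.65, limma adjusted p = 0.0254) and Ccl9 (0.75, 0.0154). Lower were the platelet integrin Itga2b (-1.10, limma adjusted p = 0.00194), Pou2f3 (-1.09, 0.0417), the type I interferon gene Ifna5 (-0.78, 0.0420), Itgb1bp2 (-0.76, 0.0344), Zfp874a (-0.66, 0.0345) and Foxp4 (-0.63, 0.0460). Acute phase and complement genes (median 0.28, camera adjusted p = 1.99e-05, 2 of 13 higher, 8 adjusted over the list alone) and B and plasma cell genes (0.24, 1.27e-04, 0 of 20 by limma, 4 adjusted over the list alone) also differed, with adjusted p = 0.0246 and 0.0466 with an estimated correlation. Type 2 airway genes had a median difference of 0.23 and did not pass (camera, adjusted p = 0.303). In all, 51 of 8014 probes were called by limma, 31 higher and 20 lower in experiment 2, and 953 had an unadjusted p under 0.05. That count depended on the hybridizations in the fit: it was 13 with scaled hybridizations, 339 with the array as a random block, and between 11 and 285 with 1 hybridization left out. It was 0 (limma) without experiment 1 in the fit, chosen after seeing the data (553 at an unadjusted p under 0.05), and 0 from these 4 hybridizations alone (725). Cxcl9, Igtp, Gbp4, Oxct2a, Adipoq and Itga2b kept their calls under scaling and with each of the 10 hybridizations left out; the other 10 named genes lost theirs in at least 1 of these.

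Across probes, the experiment means of experiments 2 and 4 had a Pearson r of 0.786, while the other 5 pairs of experiments lay between -0.0208 and 0.135; probes are not independent replicates and the 6 values carry no p. Of probes higher by limma, 735 were shared by experiments 2 and 4 against 128 expected if calls were independent, and of those lower 547 against 105. Both tests of a probe used the same error estimate, which by itself makes calls overlap, so these expectations may be too low. Ccl8, Arg1, Clca1, Timp1, Ccl9, Saa3, Muc5ac, Cxcl13, Birc5 and Matk were among the 12 highest genes of both. Gsta2, Slc7a11 and Lrat were among the 12 lowest of both.

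The question behind the series was whether a stripped array gives the ratios of a new one. In experiment 1, Il10 had ratios between 1.95 and 2.16 over the new array and the 3 stripped arrays. It had been named for passing the test with the same sign in every one of them. Some genes named by the same rule spread more, such as Zbp1 (-1.50 to -0.84) and 1700001J03Rik (0.69 to 1.60). Across all probes, r was between 0.691 and 0.762 for the 6 pairs of experiment 1 hybridizations. The new array differed from the stripped ones by a root mean square of 0.251, and stripped arrays differed among themselves by 0.279. The difference of -0.0277 had an exact permutation p of 1 (one-sided, 4 arrangements), and the smallest p the design allowed was 0.25. With each stripped array as the odd one, the difference was 0.00200, 0.0238 and 0.00196, so the new array had the lowest value. The test asked only whether the new array lay farther away. Noise added to each stripped array would lower the difference, so this p does not show that stripped arrays equal new ones.

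Pairs of hybridizations of the same experiment had a mean r of 0.673 across probes (9 pairs) and other pairs one of 0.0969 (36 pairs). The difference of 0.576 had an exact one-sided permutation p of 6.35e-04 over 3150 labelings. Most other pairs joined different treatments or tissues, so this p does not tell how well ratios outlast stripping. In experiments 2, 3 and 4 both hybridizations were on the same array, so array and experiment cannot be separated there. Between the first and the third hybridization of an array r was 0.705 in experiment 2, 0.480 in experiment 3 and 0.496 in experiment 4. The 4 pairs joining experiments 2 and 4 had r between 0.481 and 0.726. The value of 0.726 joined the new arrays of both experiments. It was above the r of either array with its own last hybridization (0.705 and 0.496). Between the last hybridizations of both experiments r was 0.505. New with last gave 0.481 for experiment 2 with 4 and 0.599 for experiment 4 with 2. These are single pairs, and their differences were not tested. In experiment 2, Ccl8 was at 3.75 ± 0.10 (SD, n = 2) over both hybridizations. The type 2 list there had a median of 1.76 on the first and 0.93 on the third hybridization. Cell cycle genes there had medians of 1.44 and 0.86. In experiment 4 these medians fell too, from 1.83 to 0.79 and from 1.22 to 0.61. For a shift common to the 3 arrays limma called 0 of 8014 probes (smallest adjusted p = 0.613), with 622 at an unadjusted p under 0.05 where chance gives about 401. With 3 differences this does not show that no shift was present.

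Standardized major axis slopes of the third on the first hybridization were 0.895, 0.984 and 1.00, with a mean of 0.961 ± 0.0580 (SD, n = 3). Such a slope is the ratio of the 2 SDs and does not measure whether single ratios were kept. Least-squares slopes were 0.631, 0.472 and 0.499 in experiments 2, 3 and 4. Probes with an absolute log2 ratio of at least 1 on the new array had, on the third hybridization, medians of 0.797, 0.406 and 0.555 of the first value. Probes chosen in the same way on the third hybridization had, on the new array, medians of 0.979, 0.903 and 0.4 of the later value, so in experiment 4 the shrinkage went both ways. A choice on 1 value lowers the other by itself. The number of probes at that size went from 263 to 183, from 166 to 57 and from 204 to 198.

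**Figure D3:**
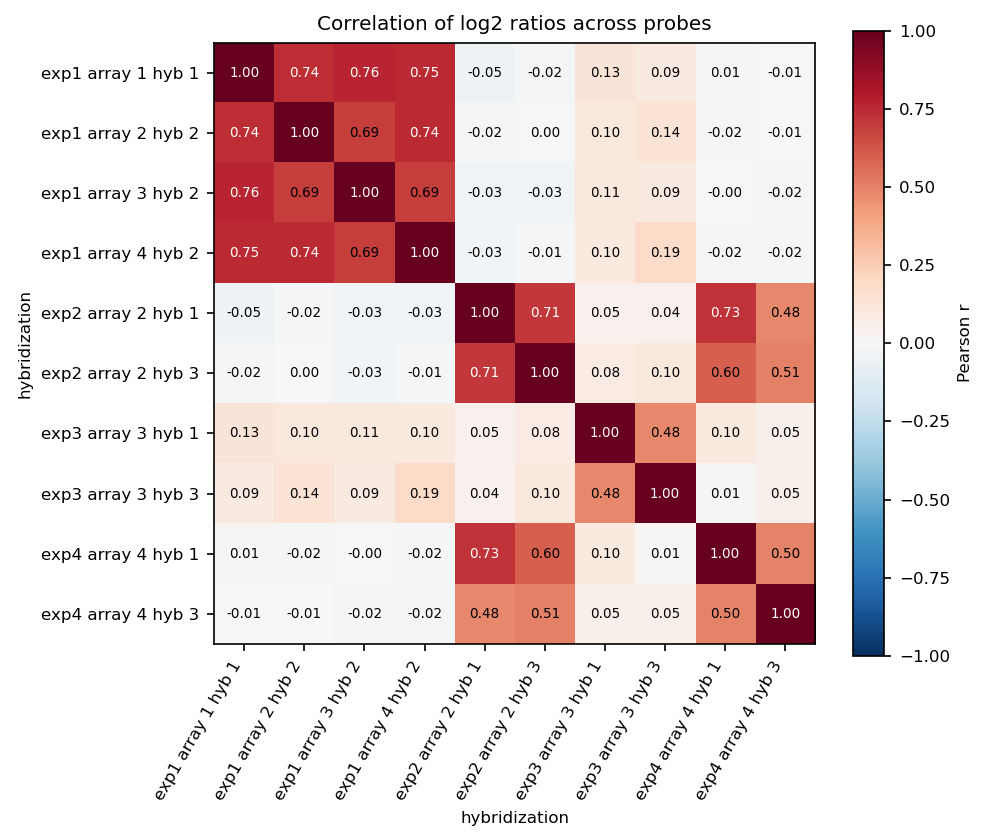
Pearson r of log2 ratios across probes for all pairs of the 10 hybridizations, in order of experiment (both axes; array and hybridization number in the labels, colour and digits give r). The block of experiment 1 lies between 0.691 and 0.762, and experiments 2 and 4 form a second block with r of 0.481 to 0.726 between them.

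Signal left from an earlier hybridization was looked for with slopes across probes. Ratios of experiment 1 on a stripped array, less the mean of the other experiment 1 hybridizations, had a mean slope of 0.00108 on the first hybridization of the same array and of -0.00533 on those of the other reused arrays. The difference of 0.00641 had an exact one-sided permutation p of 0.333, where the smallest possible was 0.167. Among probes with an absolute first ratio of at least 1 it was 0.0254, with that smallest exact permutation p (0.167). It was -0.000817 without experiment 1 replicate 2 and -0.0223 with the third hybridization, which came later, in place of the first. The change from the first to the third hybridization had slopes of 0.0375, -0.0435 and -0.0219 on the experiment 1 ratios of array 1 (mean -0.00931 ± 0.0419, SD, n = 3). Slopes on first hybridizations of experiments with another treatment were between -0.0851 and 0.0323. Between experiments 2 and 4, which share OVA induction, they were -0.209 and -0.221. These 2 are no background for carry-over, since the ratios of both experiments were correlated.

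**Figure D4:**
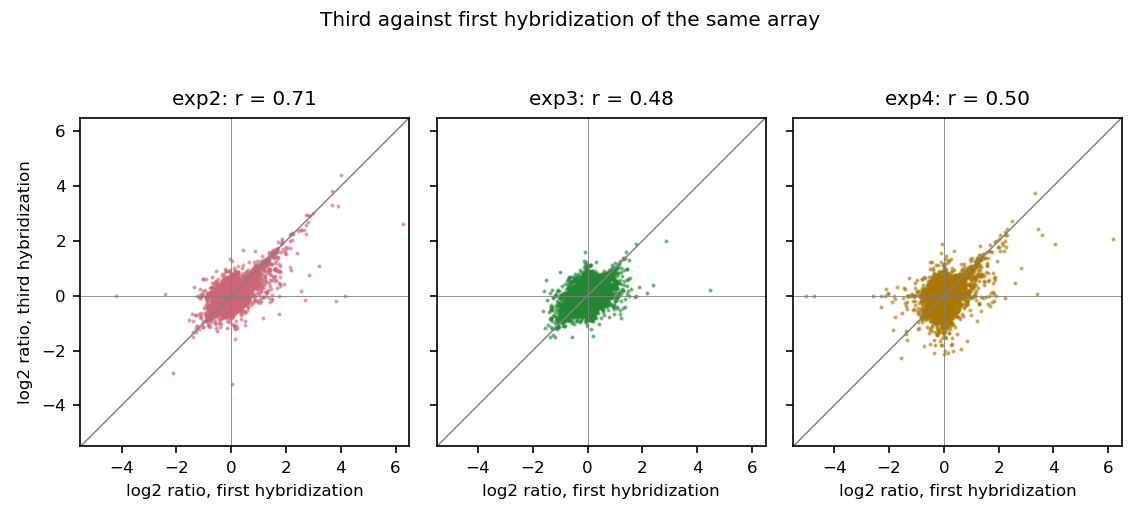
Log2 ratio of each probe on the third hybridization (vertical axis) against the first hybridization (horizontal axis) of arrays 2, 3 and 4, for experiments 2, 3 and 4; grey lines mark 0 and equality. Points along the horizontal line at 0 are probes with a large ratio on the new array and a ratio near 0 later.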

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

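The test of genotype by the Ifng ratio was chosen only after the result was seen; the other tests of the interferon pattern were set beforehand.

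Among 4 hybridizations of experiment 1, 1700001J03Rik stood apart in replicate 2, at 0.69 against 1.51 to 1.60 in the other 3. It was the single case past Dixon's 95% limit among 31 groups of 4 values, where chance gives 1.55.

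OVA induction gave different ratios in experiments 2 and 4 for 51 of 8014 probes by limma, as log2 differences of experiment 2 minus experiment 4. Of those higher in experiment 2, Cxcl9 was highest at 2.65, followed by AV064505 at 1.65. Cxcl10 was at 1.39, Igtp at 1.08, Ifng at 0.86, Gbp4 at 0.83, the chemokine Ccl9 at 0.75 and Gbp2 at 0.66. Lower in experiment 2 were Oxct2a at -1.58, the adipocyte hormone Adipoq at -1.38, the platelet integrin Itga2b at -1.10, Pou2f3 at -1.09, Ifna5 at -0.78, Itgb1bp2 at -0.76, Zfp874a at -0.66 and Foxp4 at -0.63. The count was between 11 and 285 with 1 hybridization left out, and Cxcl9, Igtp, Gbp4, Oxct2a, Adipoq and Itga2b were the 6 named genes whose limma calls held with each of the 10 hybridizations left out. Ifng, for example, was at 0.67 without experiment 2 replicate 1 (limma, adjusted p = 0.0656).

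By camera, 11 gene lists also differed between experiments 2 and 4, given as median differences. Interferon gamma response genes were at 0.30, acute phase and complement genes at 0.28 and B and plasma cell genes at 0.24, and these 3 held with an estimated correlation (adjusted p = 0.0222, 0.0246 and 0.0466). The other 8 did not. Cell cycle genes were at 0.22 (adjusted p = 0.207 with an estimated correlation), macrophage markers at 0.20, extracellular matrix genes at 0.19, interferon stimulated genes at 0.15, lung epithelium markers at -0.14 and immediate early genes at -0.16 (adjusted p = 0.0985 each with an estimated correlation for these 5 lists). MHC class II genes were at 0.17 (adjusted p = 0.150 with an estimated correlation) and hepatocyte markers, over 4 genes, at -0.30 (0.128). Without experiment 2 replicate 1 the camera calls of cell cycle (adjusted p = 0.319), macrophage (0.094), extracellular matrix (0.094), interferon stimulated (0.094), lung epithelium (0.131), MHC class II (0.181) and hepatocyte lists (0.181) ended. Without experiment 4 replicate 1 those of the matrix (0.156), interferon stimulated (0.149), lung epithelium (0.0873), MHC class II (0.156) and hepatocyte lists (0.156) did, and without experiment 4 replicate 2 that of cell cycle genes (0.072).

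The smaller OVA ratios of interferon gamma response genes in experiment 4 were weighed against 2 technical explanations and 1 biological one. A ratio near 0 gives no expression level, so these genes may have been low or high both with and without OVA. A single hybridization round was ruled out: the median difference was 0.33 between first hybridizations and 0.32 (0.322) between those of the third round, above all random lists in both, with 24 of 25 members above 0 in each. A smaller response overall was ruled out as the whole cause, since the list median stayed at 0.270 after experiment 4 was multiplied by 1.18, the slope over 963 genes called in both. Ifng itself differed by 0.86 (0.859), as the transgene on an IFN-g-/- background might give. This stays a hypothesis that cannot be told apart from any other difference between these experiments, because each genotype had 1 comparison on 1 array.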

How the results depend on the processing

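The fit without experiment 1, array quality weights and the fit without probes holding an exact 0 were chosen only after the result was seen; all other alternatives were set beforehand. Of 39 list calls, 16 kept direction and call under every alternative run for them. Named genes were rerun only without centring, with scaling and with each of the 10 hybridizations left out, and 95 of 112 kept direction and call under these. Without centring, all 39 and all 112 did. Counts of called probes stayed within 1.5 times under no centring, other probe filters, the robust prior and the fit without exact zeros.

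Other settings moved them; the cause was not tested unless stated. Scaling the hybridizations gave 13 probes for experiment 2 minus 4. The array as a random block gave 2884 in experiment 4 and 339 for the difference. Its consensus correlation within arrays was negative (-0.241). A negative value makes the mean of 2 hybridizations on 1 array count as more precise, so these higher counts are no sign of firmer results. Without experiment 1 in the fit, which leaves fewer degrees of freedom, limma called 1140, 1298 and 693 in experiments 2, 3 and 4 and 0 for the difference (553 at an unadjusted p under 0.05). Array weights gave 1179 in experiment 3. From own hybridizations alone, which leaves 1 or 2 degrees of freedom, limma called 0 in experiments 2, 3 and 4 and for the difference (2622, 1632, 1805 and 725 unadjusted), so that 88 of the 112 named genes had no call there. Experiment 4 against the mean of the other 3 gave 1184. That setting also turned the inflammatory list to -0.0581, -0.340 and -0.126 in experiments 2, 3 and 4. An estimated correlation left 18 of 39 list calls. Spearman's rho between experiments 2 and 4 was 0.673. The carry-over difference was -0.0223 on the third hybridization and 0.0254 among probes with an absolute first ratio of at least 1 (exact permutation p = 0.167, the smallest possible).

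With 1 hybridization left out, counts ranged from 2572 to 3467, 1109 to 2388, 1873 to 2184 and 923 to 2122 in experiments 1 to 4, from 11 to 285 for the difference, and from 32 to 43 for list calls; a lone hybridization is then assumed to vary like the others. The carry-over difference ranged from -0.000817 to 0.0164 and r between experiments 2 and 4 from 0.616 to 0.792. Signal over background was not analysed here, so its limit on single probes is unknown.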

Other observations

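The thresholds for ratios near 0, the tests of chance values, exact zeros, weak signal and sign changes of arrays, the count of probes without a difference between experiments and the expectation from shared calls were chosen only after the result was seen; the other tests were set beforehand.

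Some gene groups had members past the test without a shift of the list. In experiment 2 the alveolar epithelial genes Hopx (-0.80 ± 0.02, SD, n = 2) and Aqp5 (-0.71 ± 0.05) fell and the secretory gene Scgb3a2 (0.66 ± 0.16) rose, with 4 of 12 lung epithelium markers higher and 5 lower (median -0.21, limma camera adjusted p = 0.426). Extracellular matrix genes had 4 of 9 higher, including fibronectin Fn1 (1.40 ± 0.03) and the collagen cross-linking enzyme Lox (0.96 ± 0.04), and 2 lower (median 0.02, camera adjusted p = 0.274). Eosinophil and mast cell markers had 2 of 8 higher, the eotaxin receptor Ccr3 (0.89 ± 0.13) and the protease Mcpt2 (1.03 ± 0.65), and a median of 0.49 (camera, adjusted p = 0.343). NK and cytotoxic genes had 9 of 27 higher and 3 lower (median 0.17, camera adjusted p = 0.0676). Neutrophil markers had a median of 0.30 (camera, adjusted p = 0.408). Of 6 erythroid markers the globin Hba-a1 was lower (-0.86 ± 0.05; list median 0.07, camera adjusted p = 0.768), and 3 heart and skeletal muscle markers had a median of -0.99 (0.244).

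In experiment 1 the cytotoxic gene group held opposite movements: Il18rap rose while the death ligand Tnfsf10 (-1.04 ± 0.07, SD, n = 4), the granzyme inhibitor Serpinb9 (-0.99 ± 0.08) and the NK receptor Ncr1 (-0.73 ± 0.06) fell, with 6 of 27 higher and 11 lower (median -0.15, limma camera adjusted p = 0.495). MHC class II genes likewise held H2-DMb1 at -1.01 ± 0.05 and the co-stimulator Cd80 at 0.77 ± 0.10.

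Large ratios of the new arrays were often near 0 on the third hybridization. Of 633 values with an absolute log2 ratio of at least 1 on a new array, 149 (23.5%) were under 0.3 later, and of 438 such values on the third hybridization 104 (23.7%) had been under 0.3 on the new array. The ratio of 149 to 104 was 1.43, within the limit of 1.5 times set here for regression to the mean. That limit is a choice and not a property of such regression. The arrays went opposite ways (41 against 13, 52 against 15 and 56 against 76 in experiments 2, 3 and 4). The sum therefore does not decide this explanation. In experiments 2 and 4 the signs of these values on a new array were not chance alone for the set, though this does not hold for each probe. Of 97 values, 71.1% (69, exact 95% interval 61.0 to 79.9, probes taken as independent) had the same sign on the other new allergy array, or 60 of 87 probes counted once (58.1 to 78.5%). The type 2 cytokine genes Il13 (3.81 then -0.18 in experiment 2, 3.41 on the other new array) and Il5 (1.37 then -0.09) were among them. Only signs were compared, and some of the largest values were near 0 or opposite on the other new array. Examples are Gm3776 (-4.19 in experiment 2, 0.02 on the other), probe 640438 (-4.74 in experiment 4, 0.22) and Tnfsf4 (-2.60 in experiment 4, 1.29). Across all probes the new arrays of experiments 2 and 4 had a Spearman rho of 0.686, and the share of equal signs among all probes was not taken. A small real ratio with chance added would also tend to keep its sign. The share therefore does not tell whether the large size of these values was chance. Weak signal is a candidate explanation. Probes with a value under 0.3 later varied 2.10 to 2.98 times as much in experiment 1 as those with at least 0.5 in the same direction on the third hybridization. Of the 4 experiment 1 hybridizations, 3 were on these same arrays after stripping, so this spread cannot tell weak signal from an effect of stripping. For the 52 of experiment 3 chance cannot be told from signal without a new array of that treatment.

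Exact zeros were part of this pattern. On the third hybridization 7 of 41, 1 of 52 and 18 of 56 such values were exactly 0 (17.1, 1.92 and 32.1% in experiments 2, 3 and 4), against 2.86, 0.811 and 4.80% of all probes. In experiment 1, 29.3, 5.77 and 19.6% of these probes held an exact 0, against 0.495, 0 and 0% of those with at least 0.5 in the same direction on the third hybridization; ratios from 0.3 to 0.5 or of the opposite sign from 0.3 were in neither group.

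In the same direction in all 4 experiments, 67 probes were higher and 70 lower by limma, where about 3.03 and 3.17 would be so by chance if experiments were independent, or 17.4 and 16.5 with the calls shared by experiments 2 and 4 taken as given. Higher were the leukocyte receptor genes Lilr4b and Lilrb4a, the complement regulator Cfp, Cxcl10 and Csf1, and lower were Calcrl, Klf2 and Scd2, chosen after their values were seen. A dye effect and a shared response cannot be told apart for these 137 probes, since dyes were never swapped. The 4 means had a median moderated F of 7.58 (quartiles 2.84 and 19.5) and differed in 82 probes (59.9%) and not in 55. That F sets single samples against hybridization error, and sample differences may lie on top of a constant dye effect.

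For the shift from the first to the third hybridization, limma called 0 probes, and the highest count among the other sign patterns of the 3 arrays was also 0 (622 unadjusted against 294, 421 and 256). All 4 patterns thus gave as many calls, and 4 are too few for a share under 0.05.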
